A study of Arabidopsis thaliana with 6 samples.

How the data were processed

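Gene expression was measured in whole Arabidopsis thaliana seedlings of the Col-0 accession at growth stage 1.02. Per the labels, plants grew in continuous light at 23 °C on Murashige and Skoog agar of reduced strength with 0.8% agar, after stratification for 72 h at 4 °C. Biotin-labelled target made from total RNA was hybridised to oligonucleotide arrays. There were 6 arrays, each the only array of its group, titled zer, wat, glc, OMG, DOG and man. The groups were taken from those titles. The labels give no concentration and no duration for any treatment, and they do not spell the abbreviations out. The series title names glucose analogs that are not metabolised. On that basis glc is read here as glucose and OMG and DOG as the analogs. In a related publication the analogs were 3-O-methylglucose and 6-deoxyglucose. That reading of OMG and DOG comes from knowledge of that publication and not from the labels. The names wat, zer and man are kept as given. The title man could stand for mannitol or for mannose, and nothing in the sources used here settles which.

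The deposited values are probe set signals on the linear intensity scale, made with MAS5 per the submitters' processing notes; its version and settings are not given in the sources used here. In each deposited column the mean signal, after trimming 2% of the probe sets at each end, was 100, so the arrays had been scaled to a common mean before deposit. Such scaling assumes that total signal was equal between samples, and it hides any change shared by most transcripts. The table held 22810 probe sets. The 64 control probe sets were left out, and 22746 were used. Median signal ran from 40.2 (OMG) to 43.2 (zer).

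Because there was 1 array per group, no test, p-value or standard error was computed, and no difference reported here has a replicate check. For arrays, their number limits the precision. A probe set entered a comparison when its signal was at or above the median of the array in at least 1 of the 2 arrays. Signals below the 40th percentile of their array were raised to that percentile, a floor between 26.1 (OMG) and 28.8 (zer). A fold with a value at the floor is a lower bound and is written as at least N-fold. Probe sets at least 2-fold apart were counted. The 40th percentile differs slightly between arrays, so a probe set at the floor on both arrays carries a small difference that has no meaning. For scale, 100 simulations of unchanged arrays drew noise from the difference between OMG and DOG in 20 signal bins. They gave 3.4 probe sets at least 2-fold apart on average, and between 0 and 9. This is a low estimate of noise, since OMG and DOG had the smallest SD of the 15 pairs of arrays and themselves had 10 probe sets 2-fold apart.

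Probe sets were named from the platform annotation, updated through a reference gene table of assembly TAIR10.1, which was used only for names and for the chromosome or organelle of a gene. A single gene was named for 13513 probe sets, of which 13436 matched that table, several genes were named for 503, and 8730 are unnamed here. Only 1580 probe sets carried a gene symbol other than a locus identifier. Of 337 entries in 17 gene lists fixed before the data were examined, 41 had a probe set named for that gene alone. Only these are called measured. The others may be read by probe sets that are unnamed here or named for several genes. Where a gene had several probe sets, the brightest stood for it in a list. The median log2 difference of each list with at least 3 measured genes was given a percentile among 10000 random lists of the same size, matched on mean signal, as a description of these arrays. Another 15 gene families were formed from symbol prefixes after the name table was seen and before any fold was computed. Probe sets of plastid and mitochondrial genes formed 2 further groups. Plastid genes were placed by the reference gene table. Mitochondrial genes were taken as those without a chromosome in that table whose symbol began with 3 lowercase letters and then a capital or digit.

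Genes were named in the text by a rule fixed before the data were examined. It took the 10 largest folds in each direction for glc against wat, 6 for the other comparisons with wat, and 3 for each direct comparison. Candidates were at least 2-fold apart and named for a single gene, with symbols taken before loci. For comparisons with wat they also had to be at least 1.5-fold from the median of the other 4 arrays in the same direction. Up to 4 members of each gene list with the largest differences were added. The rule also asked for HXK1, the glucose-phosphorylating sensor hexokinase, in all arrays; no probe set used here is named for it alone, so its signal is not reported. Folds and signals given for any unnamed probe set fall outside the rule and were chosen after their values were seen.

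Log2 differences from wat of 2 arrays share the wat array, which alone gives a correlation near 0.5 when all arrays have equal noise. An array that lies farther from wat, as glc and zer do, lowers that value but not the shared covariance. The covariances are then the better comparison, but a wat array noisier than the simulated ones raises them without any shared change. Each correlation reported here is given with its simulated value, with the covariances, and with the correlation of 2 differences that share no array. The last was an alternative chosen after seeing the data. Probe sets called in glc were also picked against another array than wat before reading their differences from wat, and read in simulations that kept the glc values, both likewise chosen after seeing the data. Alternatives planned beforehand were quantile normalization, scaling to equal medians, a floor at the 25th percentile, a pseudocount in place of the floor, no filter, a filter on all arrays of a comparison, leaving out probe sets with shared probes, and the mean of 2 arrays as the control. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The counting step was tested on simulated data for glc against wat with 22746 probe sets, of which 50 were changed at each fold size. It recovered 44.0% of true 2-fold changes, 94.0% of 3-fold, 92.0% of 4-fold and 96.0% of 8-fold changes, and it called 6 unchanged probe sets. All changed probe sets had a signal at or above the median, so recovery among dimmer ones was not tested. The noise was the low estimate from OMG and DOG described above. Of 100 simulated lists of 10 unchanged genes, 4 fell outside the central 95% of random lists.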

Results

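Signals of 22746 probe sets were compared between 6 arrays of Arabidopsis seedlings, 1 each for the groups zer, wat, glc, OMG, DOG and man. The series title asks which genes respond to glucose analogs that the plant does not metabolise, as a way to find glucose responses that do not pass through hexokinase. The comparisons with wat therefore set each of the other arrays against the array titled wat, and direct comparisons set glc against each of OMG, DOG and man. Between 27.9% (man) and 28.5% (zer and glc) of probe sets had a signal of 100 or more. The ratio of 3' to 5' signal of the actin control, a measure of how complete the labelled RNA was, was 7.48 in zer and 6.41 in glc. It lay between 3.46 (DOG) and 4.66 (wat) on the other 4 arrays. The arrays differed less over the other control pairs. A second actin pair read 1.86 in zer, 1.76 in glc and 1.72 in man. A GAPDH pair read 1.38 in zer, 1.26 in glc and 1.35 in OMG and man.

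The genes named as lower in glc than in wat include several of amino acid breakdown, a process for which no gene list was tested. GAT1_2.1, a glutamine amidotransferase-like protein, read 508.6 in wat and 50.3 in glc, 10.1-fold lower. ASPGB1, an asparaginase, was 4.98-fold lower (186.7 and 37.5). MCCA and MCCB, the subunits of methylcrotonyl-CoA carboxylase, were 4.88-fold and 3.36-fold lower, and IVD, isovaleryl-CoA dehydrogenase, was 3.29-fold lower. These 3 genes belong to leucine breakdown. AKINBETA1, a regulatory subunit of the energy-sensing SnRK1 kinase, was 2.76-fold lower, and MGL, methionine gamma-lyase, was 3.01-fold lower. ICL, isocitrate lyase of the glyoxylate cycle, was at least 3.74-fold lower, reading 101.7 in wat and 21.0 in glc. HIS1-3, a linker histone induced by water deficit, was at least 2.87-fold lower, and the defensin gene PDF1.4 was 4.15-fold lower. The largest difference was in a probe set that is unnamed here, which read 876.1 in wat and 14.9 in glc, at least 32.2-fold lower. Another unnamed probe set was 11.6-fold lower, at 927.6 and 80.2.

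Folds were smaller among the transcripts that were higher in glc. XTH19, a xyloglucan-modifying enzyme of the cell wall, was at least 2.87-fold higher than in wat, at 82.1 against 25.3. ATPMEPCRB, a pectin methylesterase, was 2.28-fold higher. NRPA1, the largest subunit of RNA polymerase I, was at least 2.43-fold higher, and MED9, a Mediator subunit, was at least 2.08-fold higher. TPLATE, a subunit of an endocytic adaptor complex, was 2.09-fold higher, RBL was 2.34-fold higher, and CHX16, a cation/proton exchanger, was at least 2.33-fold higher. Among genes named by locus, AT4G04940 was 3.42-fold higher (30.3 in wat and 103.5 in glc), AT2G43620 was 3.18-fold higher (215.8 and 686.9), and AT2G34357 was at least 3.02-fold higher.

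Over all probe sets compared, 102 were at least 2-fold higher and 189 at least 2-fold lower in glc than in wat, of 12042. At 4-fold, 24 were lower and 0 higher. TPLATE, MED9 and ATPMEPCRB fell below 2-fold under at least 1 alternative setting, while 17 of the 20 genes named for this comparison stayed at or above it.

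**Figure D1:**
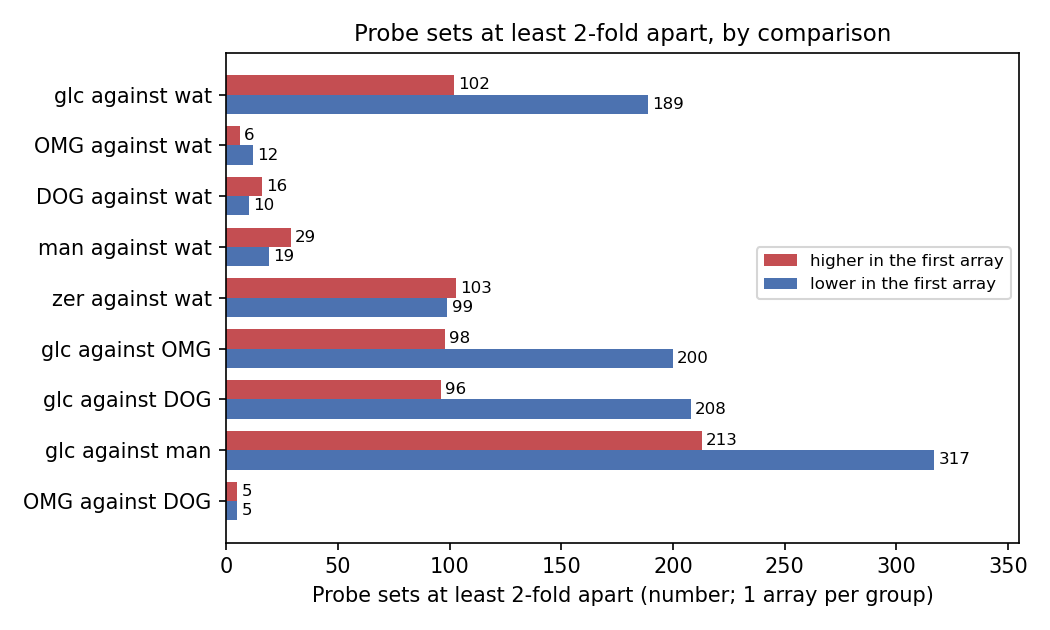
Bars give the number of probe sets at least 2-fold higher or lower in the first array of each of 9 comparisons, with 1 array per group. The 3 comparisons of OMG and DOG with wat and with each other have 5 to 16 probe sets per direction, and glc against wat has 102 higher and 189 lower.

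The preset sugar starvation and low energy list had 8 measured genes of 31, and all 8 were lower in glc than in wat, 4 of them by at least 2-fold. Its median log2 difference was -1.12, at percentile 0 of the matched random lists. Beside MCCA, MCCB, IVD and AKINBETA1, the log2 differences were -0.78 for AT3G15450, -0.68 for the autophagy gene ATG8E, -0.44 for the transcription factor gene BZIP53 and -0.20 or lower for AT5G38710, whose glc signal was at the floor. The 3' to 5' actin ratio of glc, given above, was also higher than that of wat. The other control pairs read higher in glc than in wat too, but by less.

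Other lists with measured genes stood less far from random lists in glc against wat. Of the 3 sugar transport genes, the tonoplast transporter genes TMT1 and TMT2 had log2 differences of -0.50 and -0.56 and SWEET11 one of -0.07, a median at percentile 2.67. Nuclear photosynthesis genes had a median of -0.07 over 7 genes (percentile 24.5), with LHCB4.2 at -0.26 and the Rubisco activase gene RCA at 0.17. In the list of flavonoid and anthocyanin genes, UGT78D2 had a log2 difference of 0.40, DFR -0.11 and UF3GT -0.28, with 2 of the 5 genes at the floor on both arrays. Starch and storage genes were read for 3 genes, of which APL3 and APL4 were at the floor on both arrays and SBE2.2 differed by -0.02. Among abscisic acid and osmotic stress genes, COR15B differed by -0.34, COR47 by -0.07 and LTI30 by -0.01, and COR15A was at the floor. For touch, wounding and defence, the zinc finger gene STZ differed by -0.68, WRKY53 by at least 0.39 and PDF1.2 by at least 0.36, both being at the floor in wat. Root marker genes differed by 0.38 (EXPA18), 0.24 (EXPA7) and 0.11 (PYK10), a median at percentile 84.2. Lists with fewer than 3 measured genes gave single values. Beside ICL, AIM1 of fatty acid oxidation differed by -0.28, AT4G17260 of the low oxygen list by 0.01 and the clock gene GI by -0.07. ATHSP22.0 was at the floor on both arrays. The lists for nitrogen assimilation, sugar sensing and hexokinase, ribosome biogenesis, cell cycle and seed markers had no gene with a probe set named for it alone.

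**Figure D2:**
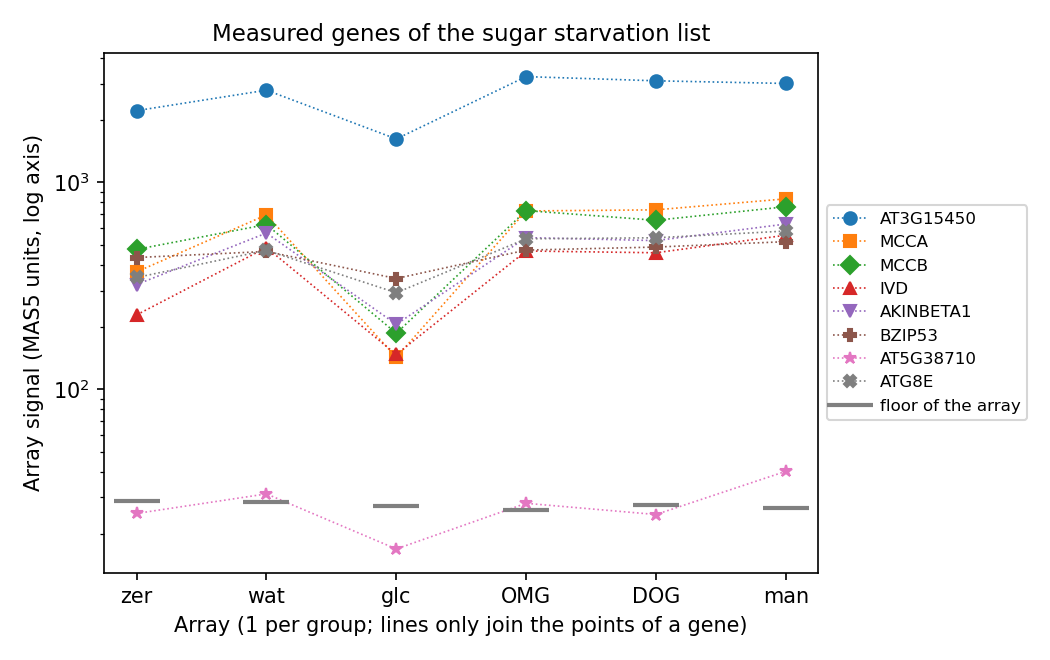
Points give the array signal in MAS5 units, on a log axis, of the 8 measured genes of the sugar starvation list on each of the 6 arrays, and grey bars mark the floor of each array. In glc each of the 8 lies lower than in wat, OMG, DOG and man; MCCA reads 142.7 in glc and 697.0 to 833.0 on those 4 arrays.

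OMG and DOG were compared with wat to ask whether glucose analogs change the same transcripts. OMG stood close to wat. CSA1, a gene for an immune receptor-like protein, read 79.0 in wat and 39.0 in OMG, 2.03-fold lower. AT1G51745 was 2.26-fold lower, AT5G18460 was 2.14-fold lower, AT5G44170 was 2.09-fold lower and AT3G57160 was at least 2.01-fold lower. No probe set higher in OMG met the naming rule. In all, 6 probe sets were at least 2-fold higher and 12 lower, of 11910, a total of 18 that ran from 3 to 45 over the alternative settings. The split turned to 11 higher and 7 lower after quantile normalization, and to 11 and 6 with equal medians; with the mean of wat and man as the control it was 0 and 7. None of these 5 named genes kept 2-fold under every alternative setting.

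DOG differed from wat in a small number of genes, among them a cell wall gene. XTH18, which encodes a xyloglucan-modifying enzyme, read 163.1 in wat and 578.9 in DOG, 3.55-fold higher. It read 252.2 in OMG and 103.9 in glc. CML41, a calmodulin-like calcium sensor, was 2.39-fold higher (60.6 and 145.1), and AT3G04010 was 2.64-fold higher. Lower in DOG were AT1G29090, by at least 2.93-fold, AT3G47380, by 2.31-fold, AT1G06000, by 2.28-fold, and AT5G44170, by 2.03-fold. Over all probe sets, 16 were at least 2-fold higher and 10 lower, of 11887, a total of 26 that ran from 8 to 45 over the alternative settings. With the mean of wat and man as the control the split turned to 3 higher and 5 lower, and CML41 (log2 difference 0.64) and AT1G06000 (-0.51) were no longer 2-fold apart. Both read much the same in man as in DOG (CML41 143.9 and 145.1, AT1G06000 70.9 and 79.2), which alone brings these differences under 2-fold. Of the 7 genes named here, 3 kept 2-fold under every alternative setting; AT3G47380 and AT5G44170 were the others that did not.

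The preset lists gave no median outside the central 95% of random lists in OMG or in DOG against wat. For the 8 genes of the sugar starvation list the median log2 difference was 0.04 in OMG (percentile 68.4) and 0.07 in DOG (percentile 91.5), with 0 genes at least 2-fold apart in either. MCCA read 728.0 in OMG and 737.0 in DOG beside 697.0 in wat, and IVD read 466.2 and 457.1 beside 484.5. The photosynthesis medians were 0.12 in OMG and 0.03 in DOG, at percentiles 93.1 and 76.0.

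Compared directly, OMG and DOG had 5 probe sets at least 2-fold higher and 5 lower, of 11833. XTH18 was 2.3-fold lower in OMG than in DOG. BHLH101, a transcription factor gene of the iron deficiency response, was at least 2.02-fold higher in OMG, AT5G58100 was at least 2.24-fold higher and AT5G55450 was 2.13-fold higher. The SD of the log2 differences between these 2 arrays was 0.213, the smallest of the 15 pairs of arrays. Without replicates no interval can be set on the difference, and the low count does not show that the analogs act alike. Whether they were given at the same dose and for the same time is not stated in the labels.

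The genes that differed in glc were then read on the analog arrays. The 102 probe sets higher in glc had a median log2 difference from wat of 1.13 in glc, 0.21 in OMG and 0.28 in DOG. The 189 that were lower in glc had a median of -1.28 in glc, -0.04 in OMG and -0.11 in DOG. A low or high reading in wat alone moves these medians the same way as glc. In simulations that kept the glc values and left the other arrays unchanged, the medians averaged 0.11 for the higher and -0.03 for the lower set in both OMG and DOG. The central 95% of simulations ran from 0.0644 to 0.158 (OMG) and 0.0645 to 0.159 (DOG) for the higher set, and from -0.0553 to -0.0101 and -0.0530 to -0.00889 for the lower. The measured medians lay beyond these ranges in the direction of glc, except for the lower set in OMG, but the simulated noise is a low estimate. With the probe sets picked against man in place of wat, the medians were -0.01 (higher) and 0.04 (lower) in OMG and -0.01 and 0.02 in DOG. Picked against the other analog they were -0.08 and 0.04 in OMG and -0.02 and 0.01 in DOG, a choice that pulls the other way if the analogs share a change. So does picking against man, if man shares a change with them. These values disagree, so whether OMG and DOG moved in the direction of glc is left open. At least 2-fold in the same direction were 2 of the 102 and 2 of the 189 in OMG, and 3 and 3 in DOG. Lists that overlapped independently would share 0.0498 and 0.185 probe sets with OMG, and 0.133 and 0.154 with DOG. Simulated unchanged arrays sharing wat gave 1.2 (OMG) and 1.14 (DOG) probe sets over both directions, so part of the overlap may come from the shared array. Those arrays had about 3.4 calls each, far fewer than glc, so that part cannot be sized from them.

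**Figure D3:**
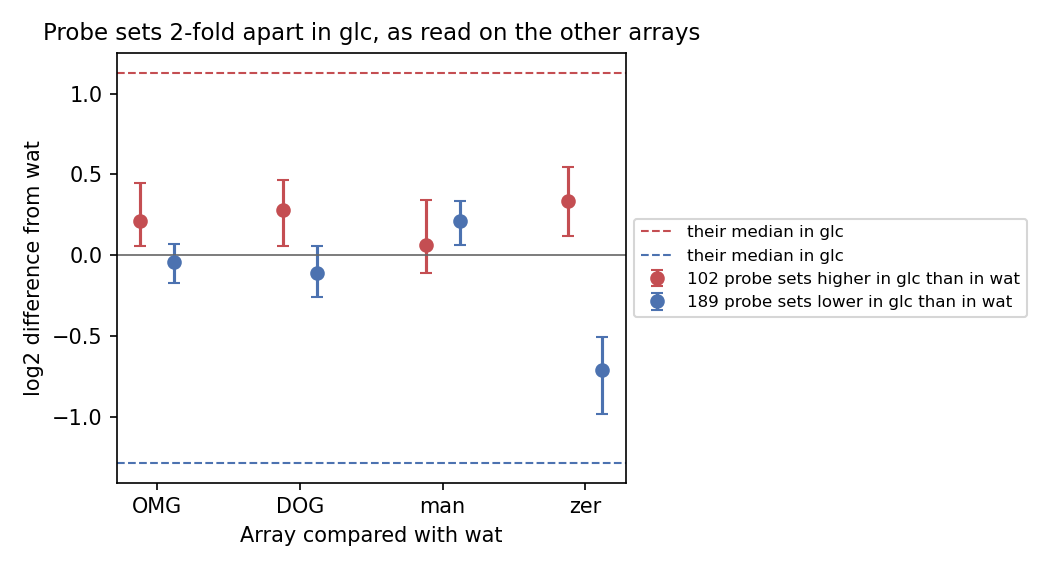
Points give the median log2 difference from wat, with bars from the lower to the upper quartile, of the 102 probe sets at least 2-fold higher in glc and the 189 lower in glc, as read on OMG, DOG, man and zer. Dashed lines give their medians in glc, 1.13 and -1.28; the lower set has a median of -0.04 in OMG, -0.11 in DOG, 0.21 in man and -0.71 in zer. Picking and reading share the wat array.

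Across probe sets, which are not independent replicates, the differences from wat of glc and OMG correlated with r = 0.297, and those of glc and DOG with r = 0.294; 7 such pairs were computed. Simulated unchanged arrays that share wat gave 0.50 and 0.499, but they lack the wider spread of glc, so these values are too high a mark. The covariances were 0.0300 and 0.0298, beside 0.0228 and 0.0227 simulated. Noise of the wat array enters these covariances, and the simulation took its size from the difference between OMG and DOG. The SD of the log2 differences from wat was 0.244 (OMG) and 0.246 (DOG), beside 0.213 between OMG and DOG. A wat array noisier than simulated would raise the covariances without a shared change, so their excess cannot decide. With no shared array, taking glc minus man in place of glc minus wat, the correlations were -0.019 for OMG and -0.026 for DOG, where unchanged arrays gave -0.0216 to 0.0150 and -0.0221 to 0.0169. Taking man lowers these values if OMG or DOG share a change with man. The differences from wat of OMG and DOG had covariances with that of man of 0.0324 and 0.0332, beside 0.0229 and 0.0228 simulated. The same limit from the noise of wat holds for them. OMG and DOG correlated with each other at r = 0.618, beside 0.501 simulated, with a covariance of 0.0369 beside 0.0228. The simulated noise came from the difference between OMG and DOG, the smallest of the 15 pairs, so both values had to exceed the simulated ones. Their excess is therefore no evidence of a change shared by OMG and DOG. With no shared array, OMG minus wat and DOG minus man correlated at 0.069, above the simulated upper bound of 0.0164. Turned in sign, the same value is the correlation of OMG minus wat with man minus DOG (-0.069), so it can equally be read as OMG and man lying on opposite sides. For simulated unchanged arrays sharing wat, which had fewer calls, the overlap was 1.21 over both directions. OMG and DOG shared 2 probe sets at least 2-fold higher and 2 lower than in wat. The named ones were PDF1.2b and AT1G70985 (higher) and AT5G44170 and AT1G29090 (lower), which were named after their values were seen. In glc, AT1G70985 was also higher than in wat (109.7 and 38.5) and AT1G29090 lower (21.2, under the floor, and 81.1). PDF1.2b (114.0 and 89.5) and AT5G44170 (71.6 and 83.5) were under 2-fold there. For AT1G70985 wat read lowest of all arrays, so a low wat reading cannot be told apart from a shared change.

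Direct comparison of glc with the analogs gave counts close to that with wat. Against OMG, 98 probe sets were at least 2-fold higher and 200 lower in glc, of 11997. Against DOG, 96 were higher and 208 lower, of 12016. GAT1_2.1 was 11.7-fold lower in glc than in OMG and 10.6-fold lower than in DOG, and ASPGB1 was 5.18-fold and 5.31-fold lower. MCCA was 5.10-fold lower in glc than in OMG, and XTH18 was 5.57-fold lower in glc than in DOG. ATPMEPCRB was 2.48-fold higher in glc than in OMG and 2.16-fold higher than in DOG. XTH19 (2.37-fold) and CHX16 (2.2-fold) were higher than in OMG, and PPR336, a pentatricopeptide repeat protein gene, and RBL were higher than in DOG, by 2.46-fold and 2.03-fold. All 8 genes of the sugar starvation list were lower in glc than on either analog array, with medians of -1.20 against OMG and -1.14 against DOG, although AT5G38710 was at the floor in both glc and DOG. Of the probe sets called against wat, 134 of 189 lower and 29 of 102 higher were at least 2-fold apart in glc from each of wat, OMG, DOG and man. Only 30 and 18 of these were also 2-fold apart from zer in the same direction.

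In man, the defensin transcripts PDF1.2 and PDF1.2b and a few plastid-encoded transcripts were higher than in wat. The defensin gene PDF1.4 was not, at 251.7 in man and 254.2 in wat. PDF1.2, a defensin gene used as a marker of jasmonate and ethylene signalling, was at least 6.26-fold higher, at 178.9 against 27.2. PDF1.2b was 5.95-fold higher (532.8 and 89.5); its probe set shares probes with related genes, so the copies cannot be separated. The plastid transcripts rpoB, rps14, petD and ndhE were 3.57-fold, 3.27-fold, 3.16-fold and 2.59-fold higher. The expansin gene EXPA15 was 2.24-fold lower and TTN9 2.05-fold lower. Among loci, AT1G06000 was 2.54-fold lower, AT5G33370 2.24-fold, AT3G61820 2.13-fold and AT3G55690 at least 2.33-fold. Altogether 29 probe sets were at least 2-fold higher and 19 lower, of 11910; after quantile normalization 37 were higher and 13 lower, and with equal medians 40 and 11. The total of 48 was less stable than that, running from 26 with the filter on both arrays to 95 with the mean of wat and zer as the control. Of the 12 genes named here, 6 kept 2-fold under every alternative setting.

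The sugar starvation list lay on the other side of wat in man. All 8 genes read higher than in wat, none by 2-fold, with a median log2 difference of 0.23 at percentile 99.8. The touch, wounding and defence list had a median of 0.49 over 3 genes (percentile 99.8), made up of PDF1.2, STZ at 0.49 and WRKY53 at 0.11 or more. The abscisic acid and osmotic stress list had a median of 0.16 over 4 genes (percentile 92.5), with COR15B at 0.47 and LTI30 at 0.18. Photosynthesis genes had a median of -0.08 (percentile 11.1). Between glc and man 213 probe sets were at least 2-fold higher and 317 lower, of 12081, the highest count of the 15 pairs. GAT1_2.1 was 15.7-fold lower in glc than in man, ASPGB1 6.23-fold and MCCA 5.84-fold. GSTU20, a glutathione transferase gene, was 2.84-fold higher, CHX16 at least 2.49-fold and PRA1.B4 2.46-fold. The differences of glc and man from wat correlated with r = 0.030, beside 0.501 for simulated unchanged arrays, which lack the wider spread of glc. The covariance was 0.0033 beside 0.0228 simulated. With no shared array (glc minus OMG and man minus wat) r was -0.256, below the simulated range of -0.0189 to 0.0191. Taking OMG there lowers r if OMG and man share a change.

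The zer array, which the labels describe no further, was compared with wat in the same way. The transcripts higher in zer included 2 cold-regulated genes. COR15B was 3.16-fold higher and COR15A at least 2.94-fold higher; both encode chloroplast proteins induced by cold. The expansin gene EXPA8 was 2.90-fold higher, GSTU20 2.79-fold, XTH19 at least 2.64-fold and the plastid transcript petD 2.71-fold. petD lost 2-fold (0.61) when the mean of wat and man was the control. It was itself higher in man, at 190.2 beside 163.0 in zer and 60.2 in wat, which alone brings that difference under 2-fold. Lower in zer were the transcription factor gene WRKY6 (2.73-fold), GAT1_2.1 (2.71-fold), the ubiquitin ligase gene ATL8 (2.61-fold), the glycosyltransferase gene UGT73C1 (at least 2.39-fold), SUFE2 of iron-sulfur cluster assembly (2.37-fold) and ASPGB1 (2.28-fold). In total 103 probe sets were at least 2-fold higher and 99 lower, of 12027.

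Among the lists, abscisic acid and osmotic stress genes had a median of 1.02 in zer against wat over 4 genes (percentile 100), with COR15A and COR15B at least 2-fold higher, LTI30 at 0.49 and COR47 at -0.01. All 8 genes of the sugar starvation list were lower in zer, IVD by at least 2-fold, with a median of -0.42 at percentile 0.01. The anthocyanin gene DFR differed by 1.4, at 106.8 in zer and 40.6 in wat. STZ differed by -1.06. The starch and storage list had a median of 0.02 at percentile 99.6, but 1 of its 3 genes was at the floor on both arrays and the sign turned with equal medians (-0.019). The 3' to 5' ratio of zer was the highest of the 6 arrays in every control pair, not only for actin. A second GAPDH pair read 1.16 in zer and between 0.84 (DOG) and 0.94 (man) on the others. Whether RNA integrity shaped the differences of zer from wat was not tested. Of the 189 probe sets lower in glc than in wat, 46 were also at least 2-fold lower in zer, and 7 of the 102 higher ones were higher, beside 1.51 and 0.850 for independent lists; 0 were 2-fold apart in the opposite direction. Simulated unchanged arrays sharing wat gave 1.18 over both directions. Those arrays had about 3.4 calls each, so 1.18 is no measure for lists as long as these. The differences of glc and zer from wat correlated with r = 0.540 beside 0.501 simulated, with a covariance of 0.0816 beside 0.0228. The simulated arrays lack the wider spread of glc and zer, so the covariances are the better comparison. A wat array noisier than simulated raises the measured covariance as well.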

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

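The settings were planned before the data were examined, except the differences that share no array, the probe sets picked in glc against an array other than wat, and the lists without members at the floor on both arrays, which were chosen after seeing the data. No paired analysis was possible because each group had 1 array. The counts for glc against wat (208 to 336 over the alternatives), and those for glc against OMG, DOG and man, stayed within 1.5 times their value under every alternative run; the mean of 2 arrays as control was run for comparisons with wat only. The counts for OMG, DOG, man and zer against wat and for OMG against DOG did not, and the cause was not tested. With a floor at the 25th percentile the counts were 45 for OMG against wat (18 in the report), 45 for DOG (26), 75 for man (48) and 25 for OMG against DOG (10). With a pseudocount they were 17 for DOG and 27 for man. A filter on both arrays, which tests fewer probe sets, left 3 for OMG, 8 for DOG, 26 for man, 130 for zer (202) and 5 for OMG against DOG, and leaving out shared probe sets also left 5 for OMG against DOG. With the mean of 2 arrays as control, 7 were left for OMG, 8 for DOG and 95 for man. The correlation of glc and OMG was 0.324 after quantile normalization, 0.327 without a filter, 0.261 with the filter on all arrays and -0.019 with no shared array. For glc and DOG it was 0.315 without a filter, 0.246 with the stricter filter and -0.026 with no shared array. OMG and DOG gave 0.634 after quantile normalization and 0.069 with no shared array. For glc and man the values were 0.055 after quantile normalization, 0.004 with a pseudocount, 0.074 without a filter, -0.029 with the stricter filter and -0.256 with no shared array. Removing the shared wat array takes away the correlation it adds. Of 74 medians on OMG, DOG, man and zer of the probe sets called in glc, 52 stayed within their bootstrap range, 10 moved outside it and 12 changed sign. For the set lower in glc, OMG gave 0.036 with equal medians and 0.011 with the stricter filter. Picked against another array than wat, the higher set gave -0.08 (DOG) and -0.01 (man) in OMG, -0.017 (OMG) and -0.013 (man) in DOG, and -0.099 (OMG) and -0.135 (DOG) in man. The lower set gave 0.039 (DOG) and 0.036 (man) in OMG, and 0.013 (OMG) and 0.019 (man) in DOG. Of 240 list medians, 220 stayed within their bootstrap range, 19 moved outside it and 1 that lay outside the central 95% of random lists changed sign, starch and storage genes in zer (-0.019 with equal medians). Of 90 medians of the ATG8, aldehyde dehydrogenase and plastid ribosomal protein families, 88 stayed within theirs, and 0 of those outside the central 95% of random lists changed sign. Of 60 medians of plastid and mitochondrially encoded genes, 41 stayed within their bootstrap range, 19 moved outside it and 0 reversed. Of 445 values for named genes, 42 fell below 2-fold, for 25 of the 78 results, and 0 changed direction. Signals near the floor limit what can be read: 36 of the 291 folds for glc against wat and 7 of the 18 for OMG are lower bounds.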

Other observations

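Gene families formed from symbol prefixes add to the account of glc; their members named here were chosen after their values were seen. Of 7 measured ATG8 genes, which encode ubiquitin-like proteins of autophagy, 6 read lower in glc than in wat, with a median log2 difference of -0.41 at percentile 0.485. ATG8F differed most, at 994.0 in wat and 596.6 in glc, and none reached 2-fold. In man all 7 read higher than in wat, with a median of 0.20 at percentile 98.7. In OMG and DOG the medians were 0.04 and 0.07. Of 8 aldehyde dehydrogenase genes, ALDH6B2, which acts in valine breakdown, and ALDH7B4 were at least 2-fold lower in glc, reading 445.2 and 431.4 beside 1020.1 and 955.1 in wat. The median of that family was 0.08, at percentile 66.5. The sugar transporter gene SWEET2 was the only one of 14 SWEET genes at least 2-fold from wat in glc, at 395.1 in wat and 176.2 in glc.

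Among 23 expansin and XTH genes, 1 was at least 2-fold higher in glc (XTH19), 1 in DOG (XTH18) and 2 in zer (EXPA8 and XTH19), each against wat, while EXPA15 was lower in man and XTH18 lower in zer. Other calls against wat were GSTU20 (higher in zer), CML41 (higher in DOG and man, lower in zer), rps14 of the plastid ribosomal proteins (higher in man and zer), and UGT73C1 and bZIP44 (lower in zer). The 15 plastid ribosomal protein genes had medians of 0.13 in OMG (percentile 99.0) and 0.22 in zer (percentile 99.8). The BGLU, SCPL, TBL, TET, CYP, and GH3 and IAA families had 0 genes at least 2-fold apart in any comparison with wat. In those 6 families and in the UGT, SWEET, GSTU, bZIP, CML and expansin families several genes lay at the floor, so their percentiles are not given. The 69 plastid-encoded genes had medians of 0.17 in OMG and in zer, 0.08 in glc and man, and 0.009 in DOG against wat. The percentiles were 100 in OMG and in zer, 93.1 in glc, 99.6 in man and 87.5 in DOG. Random lists are matched on signal only, so genes that move together on 1 array can reach an extreme percentile with a small shift. The plastid ribosomal protein genes overlap with the plastid-encoded ones (rps14 is in both), so these are not separate results. Of 16 mitochondrially encoded genes 0 were 2-fold apart from wat on any array.

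Of the tests below, those on the 3' to 5' ratios, on the number of glc arrays and on the plastid transcripts were chosen after the result was seen. A first pattern is the number of probe sets apart from wat in glc (291) beside OMG (18), DOG (26) and man (48). Noise of dim probe sets would leave few calls among bright ones, but in the brightest 25% of probe sets 161 were called in glc and at most 9 on the other 3 arrays. RNA degradation in the glc sample stays open, since the 3' to 5' ratio of glc exceeded those of wat, OMG, DOG and man in 3 of the 5 control pairs. The margin was small in the second actin pair (1.76 beside 1.72 in man) and the ubiquitin pair (1.85 beside 1.84 in wat). The count of 3 and its limits were set with the ratios already known. That count replaced a comparison with zer over the probe sets called in glc, which was set aside because those probe sets were picked by their glc values. A difference between the single glc sample and the others that is not due to glucose cannot be told apart from the treatment, since there was 1 glc array.

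A second pattern is that zer and glc lay on the same side of the other 4 arrays, with 46 probe sets lower in both than in wat. Sharing the wat array is argued against by a correlation of 0.327 between glc minus OMG and zer minus wat, where the upper bound for simulated unchanged arrays was 0.021; Spearman's rho was 0.268. For common labelling or hybridisation of zer and glc the spiked-in controls were read, over which these arrays were the farthest apart of the 15 pairs (rank 15). The distances ran only from 0.124 to 0.235 (root mean square of log2), and no arrays known to share a batch were at hand. The test therefore cannot decide, and that explanation stays open. RNA integrity of the zer and glc samples stays open, since these arrays had the highest 3' to 5' ratios in 3 of the 5 control pairs. The ratio of zer alone was the highest in every control pair. No biological explanation was tested.

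The last pattern is that 5 plastid-encoded probe sets, ndhE, petD, ndhF, rpoB and rps14, were at least 2-fold higher in man than in wat, and all 5 also in zer. More chloroplasts or more plastid RNA of every kind, by 2-fold or more, would have brought most of the 69 plastid-encoded probe sets to 2-fold, and 5 reached it. The other 64 had a median log2 difference of 0.058. They lay under 2-fold because the 5 were picked as those at or above it, so a smaller general rise is not argued against. An array-wide scaling shift is argued against by quantile normalization, after which 5 of the 5 were still at least 2-fold higher. Low readings on the wat array alone are argued against by petD, rpoB and rps14, 3 of the 5, which were at least 2-fold higher in man than in each of wat, glc, OMG and DOG. For ndhE that explanation stays open. ndhF read 66.4 in man and was not 2-fold higher there than in DOG (58.7) or OMG (35.7). It read lower in glc (24.0) than in wat (31.8), near the floor, so it cannot decide. A shift of all 69 plastid-encoded genes in man had been weighed first, but its median was only 0.08 (percentile 99.6), the nuclear photosynthesis genes had a median of -0.08, and the mitochondrially encoded genes lay too near the floor to decide, so it was set aside for these 5.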
